A study of Mus musculus with 6 samples.

How the data were processed

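RNA was sequenced from CD4-positive, CD44-positive T cells of mouse spleen, 8 days after infection with lymphocytic choriomeningitis virus. The cells were sorted on Ly6c and PSGL-1 into 3 populations. LOLO cells were low for both proteins, LOHI cells were low for Ly6c and high for PSGL-1, and HIHI cells were high for both. By the order in the series title, LOLO cells are taken as follicular helper cells, LOHI cells as precursors of central memory and HIHI cells as terminally differentiated Th1 effectors. Each population came from wild-type mice and from mice whose loxP-flanked Stat3 gene is deleted in part by a Cd4-driven Cre recombinase, which gives 6 groups. Each group had 1 library.

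Gene-level tables of pairwise comparisons were used, with FPKM (fragments scaled by transcript length and by mapped fragments) that the authors deposited per the file headers. The columns have the layout of Cuffdiff output, but the program and its version are not given in the sources used here. The submitters' processing notes name Bowtie 0.12.8 and the mouse build mm9. 1 table holds all 15 pairs of the 6 libraries for 37980 Ensembl genes, and another holds only the pair of LOLO libraries. The FPKM values of the 37899 genes usable in both deposited tables were identical, with 0 differing values. The deposited tables also hold a p-value, a q-value and a significance mark per gene and pair. Of these, only the marks are reported, as counts and for some named genes in LOLO. The threshold behind the marks and the handling of strand are not given in the sources used here. The number of per-sample columns left unused was 0. The locus column gives the span of overlapping gene models as a whole, with a start that counts from 0. End minus start equalled the gene length of the GENCODE M21 annotation for 13973 genes, and fell 1 short of it for 334. That annotation is on another build, so only its lengths and gene names were used.

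FPKM does not carry depth, but genes below 0.5 FPKM in a pair of libraries lay on steps of whole reads, so relative depth could be read from the most frequent ratio. The ratios of the 15 pairs fitted together within 7.12e-05 percent. Relative to the wild-type LOHI library, the depth was 0.411 in wild-type LOLO, 0.614 in wild-type HIHI, 0.803 in the LOLO library labelled STAT3-deficient, 0.871 in its LOHI counterpart and 0.811 in its HIHI counterpart. Absolute depth is unknown, so no counting intervals are given, and low values in the wild-type LOLO library are the least precise.

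A difference was taken as log2((FPKM + 1)/(FPKM + 1)), which understates the difference of low genes. A gene was counted when its higher library had at least 5 FPKM and the authors' status for the pair was neither FAIL nor HIDATA. A size of at least 2-fold on this scale was the threshold. In 192 gene-library values of 87 genes, deposited pairs disagreed because some listed the gene at 0. The highest value was used for the values per library. None of these was a gene of the fixed lists. With 1 library per group, no p-value was computed for a difference between libraries, and no difference has a replicate check. A one-sided Fisher's exact test across genes served only as the preset criterion for the test of exchanged labels, and its result is not printed because genes are not replicates.

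20 gene lists were fixed before the data were examined: follicular helper (Tfh), Th1 effector, memory precursor, type I interferon response, STAT3 target, IL-2 and STAT5 response, cell cycle, T cell receptor signalling, dissociation and immediate-early, inhibitory receptor, trafficking receptor, Th2, Th17, regulatory T cell, glycolysis, B cell, plasma cell, myeloid cell, CD8 T and NK cell, and erythroid cell. Of their 317 symbols, 316 matched a gene of the table. A member was measured when either library had at least 1 FPKM. The median difference of the members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called apart below the 2.5th or above the 97.5th percentile, as a description of these libraries and not as a test of the genotype. Lists with under 3 measured members got no median.

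The genes named were fixed by rule before the data were examined: Stat3, the genes of the sort (Ly6c1, Ly6c2, Selplg, Cd4 and Cd44), the markers Bcl6, Cxcr5, Il21, Tbx21, Ifng, Il2ra and Prdm1, the 8 largest differences each way in each comparison, up to 4 members of each list with the largest absolute difference, and genes at least 2-fold apart the same way in all 3 populations. Gene models without an ordinary symbol and immunoglobulin or T cell receptor segments were left out of the 8 largest. The pattern that recognises such models, among them small RNAs such as snoU and n-R5s, was written after the data were seen. Any other gene is named as chosen after its values were seen. Some genes that the rule names are not reported here.

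Both steps were tested on simulated data made from the wild-type LOLO and LOHI libraries, over 14221 genes. The 2-fold count recovered 7.14 percent of genes seeded at 1.5-fold, 70.0 percent at 2.5-fold and 100.0 percent at 4-fold, against 6.52, 78.9 and 99.9 percent expected from the noise put in. A first bound for the 2.5-fold genes, set by guess, was missed, and the share expected from the noise took its place. Among unchanged genes, 0.0733 percent passed. Of 100 unchanged lists of 25 genes, 6 percent were called apart. The noise put in was assumed, with the same relative size for every gene and independent between genes. Without replicates the real noise is unknown, so these rates need not hold for the real counts and lists. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

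The alternatives were pseudocounts of 0.1 and 5, minimums of 1 and 20 FPKM and none, FPKM rescaled to a median difference of 0 or to equal sums, other bins or unmatched random lists, and the LOLO table in place of the full one. Added after the data were seen were pairs of status OK only and counts without short or unnamed models, receptor segments, mitochondrial genes and the lists of other cell types. Scaling to equal sums moved the median difference of all counted genes by over 0.1 in the comparisons with the HIHI library labelled STAT3-deficient. These medians went to -0.31, 0.47 and 0.43, from -0.08, 0.14 and 0.12. The LOLO genotype comparison had a median of 0.12. When its median difference was set to 0, its genes at least 2-fold apart went from 715 higher and 358 lower to 617 and 434. Of 180 list medians, 8 turned direction under a scaling, none of them described by direction here unless so stated.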

Results

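RNA of CD4-positive T cells was profiled in 6 libraries, 1 from each combination of 3 sorted spleen populations and 2 genotypes, 8 days after viral infection. The populations were LOLO (follicular helper T cells), LOHI (central memory precursors) and HIHI (terminal effector Th1 cells). Values are FPKM of the authors' deposited tables. Summed FPKM lay between 1255670 and 1588210 per library, and 13906 to 14203 genes had at least 1 FPKM. Relative depth ranged from 0.411 in wild-type LOLO to 1 in wild-type LOHI. No group had a replicate, so no difference below has a replicate check, and each describes a pair of libraries.

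Stat3, the targeted gene (mm9 chromosome 11, 100720665 to 100800854, the span of its locus with any overlapping gene models), was measured at 240 FPKM in wild-type LOLO, 209 in LOHI and 156 in HIHI. The libraries labelled STAT3-deficient held 215, 181 and 187 FPKM. The log2 difference by genotype was -0.15 in LOLO, -0.20 in LOHI and 0.26 in HIHI, where the last was 0.03 once libraries were scaled to equal sums. A conditional allele loses only part of its gene, and which part is not given in the sources used here. The gene-level value therefore does not check the deletion, and in HIHI it was not lower in the library labelled STAT3-deficient. The genotype is written below as that of the library labelled STAT3-deficient. Every genotype direction, and every difference between populations within a genotype, rests on the labels.

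The genes of the sorted proteins were measured in every library. Ly6c2, which encodes a Ly6C antigen, was at 9.75, 46.0 and 1567 FPKM in wild-type LOLO, LOHI and HIHI. In the libraries labelled STAT3-deficient it was at 29.7, 42.1 and 2181 FPKM. Ly6c1 was at 25.2, 32.7 and 250 FPKM in wild type and 34.9, 33.3 and 314 FPKM in the labelled libraries. Selplg, the gene of PSGL-1, was at 82.1, 386 and 290 FPKM in wild type and 25.6, 253 and 480 FPKM in the labelled ones. Cd4 lay between 493 and 738 FPKM and Cd44 between 79.99 and 115 FPKM across the 6 libraries.

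The LOLO genotype comparison asks how follicular helper cells differ by the genotype of STAT3, a transcription factor that transmits IL-6 and IL-21 signals. In the LOLO library labelled STAT3-deficient, Tfh genes were lower, while Th1, interferon-response and cell cycle genes were higher. Bcl6, the lineage-defining repressor of Tfh cells, was at 29.2 FPKM against 75.5, a log2 difference of -1.34. Gzmb, a cytotoxic granule protease, was at 39.4 FPKM against 1.29, and Ifit3, an interferon-induced antiviral gene, at 67.8 against 1.65. Of 11248 genes counted, 1073 differed at least 2-fold, 715 higher and 358 lower. Counted without short or unnamed models, receptor segments, mitochondrial genes and markers of other cells, a restriction chosen after the data were seen and called ordinary genes below, 478 of 8386 differed, 370 higher and 108 lower.

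Of the 25 Tfh genes, 8 were at least 2-fold lower and 0 higher, with a median log2 difference of -0.83 that lay below all random lists (percentile 0). Besides Bcl6, these included Angptl2 (24.5 against 90.9 FPKM), Ascl2, a transcription factor that induces Cxcr5 (3.50 against 13.9), and Il4 (4.87 against 14.9). Il21, the helper cytokine of germinal centre B cells, was at 64.3 FPKM against 160, and Cxcr5, the receptor that guides cells into follicles, at 114 against 210. The STAT3 target list shares Bcl6, Il21, Icos, Maf, Batf, Il6ra and Il6st with the Tfh list. It had a median of 0.07 at percentile 28.1 that turned negative when the median difference was set to 0. Its members went both ways: Maf was at 56.0 FPKM against 108, and Il10 at 5.46 against 0.805.

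Of the 31 Th1 effector genes, 22 were at least 2-fold higher and 0 lower, with a median of 1.48, above all random lists. Gzmb led them, followed by the chemokine Ccl3 (39.6 against 2.501 FPKM), the granzyme Gzmk (182 against 16.3) and the chemokine Ccl5 (387 against 42.2). Tbx21, which encodes the Th1 regulator T-bet, was at 44.9 FPKM against 15.8. Ifng differed by 0.54, short of 2-fold, at 245 FPKM against 168. Eomes, a T-box factor related to T-bet, was at 33.4 FPKM against 3.21, and Xcl1, a chemokine for dendritic cells, at 56.2 against 3.63. Prdm1, which encodes the Bcl6 antagonist Blimp-1, was at 5.25 FPKM against 0.675. Il2ra, the high-affinity IL-2 receptor chain, was at 5.69 against 2.12.

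Of the 52 interferon-response genes, 41 were at least 2-fold higher and 0 lower, with a median of 1.32, above all random lists. After Ifit3 came Ifit1 (38.9 against 4.63 FPKM), Ifi44 (18.3 against 2.16) and Rsad2, an antiviral enzyme (34.1 against 5.06). Of the 33 cell cycle genes, 27 were at least 2-fold higher and 0 lower, with a median of 1.19. Plk1, a mitotic kinase, was at 38.5 FPKM against 12.3, and Kif11, a spindle motor, at 36.8 against 11.8. The IL-2 and STAT5 response (median 0.69), trafficking receptor (0.83), Th2 (1.01) and regulatory T cell (0.39) lists also lay above the central range of random lists. Cish, a feedback inhibitor induced by STAT5, was at 15.1 FPKM against 4.11. The inhibitory receptor list (median -0.43) lay below the central range of random lists, although its member Havcr2 was at 3.91 FPKM against 0.236. The T cell receptor signalling list also lay below it, with a median of -0.17 and Egr1 at 39.8 FPKM against 104. The memory precursor (0.29), glycolysis (-0.07), Th17 (-0.11) and dissociation and immediate-early (0.26) lists were not apart. Satb1, a chromatin organiser, was at 18.3 FPKM against 70.8 within the memory precursor list.

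Transcripts of other cells and organelles differed in the same pair. The erythroid list had a median of -5.26: Hba-a1, an alpha-globin gene, was at 51.4 FPKM against 2001 in wild-type LOLO, and Hbb-b1 at 39.0 against 1844. Mitochondrial genes took 5.32 percent of summed FPKM against 14.2 percent. Igkc, the kappa light chain constant region, was at 1599 FPKM against 264, and the myeloid list had a median of -0.86. The CD8 T and NK cell list (0.29, 3 members measured) was not apart, and the B cell list had a median of -0.36 below the central range of random lists. Art3 (115 against 8.70 FPKM) and Plac8 (149 against 14.0) were among the 8 highest genes. Lmbr1 (0.712 against 76.5 FPKM), Padi4 (6.09 against 74.99) and Apol11b (0.801 against 15.4) were among the 8 lowest. The authors' deposited table of all 6 libraries marks 224 genes for this pair, 159 higher and 65 lower. The authors' deposited table of the LOLO libraries alone marks 1349 from the same FPKM, 912 higher and 437 lower. Among the genes named above, the table of all 6 libraries marks Gzmb, Ifit3 and Prdm1 but not Bcl6, Cxcr5, Il21 or Tbx21.

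**Figure D1:**
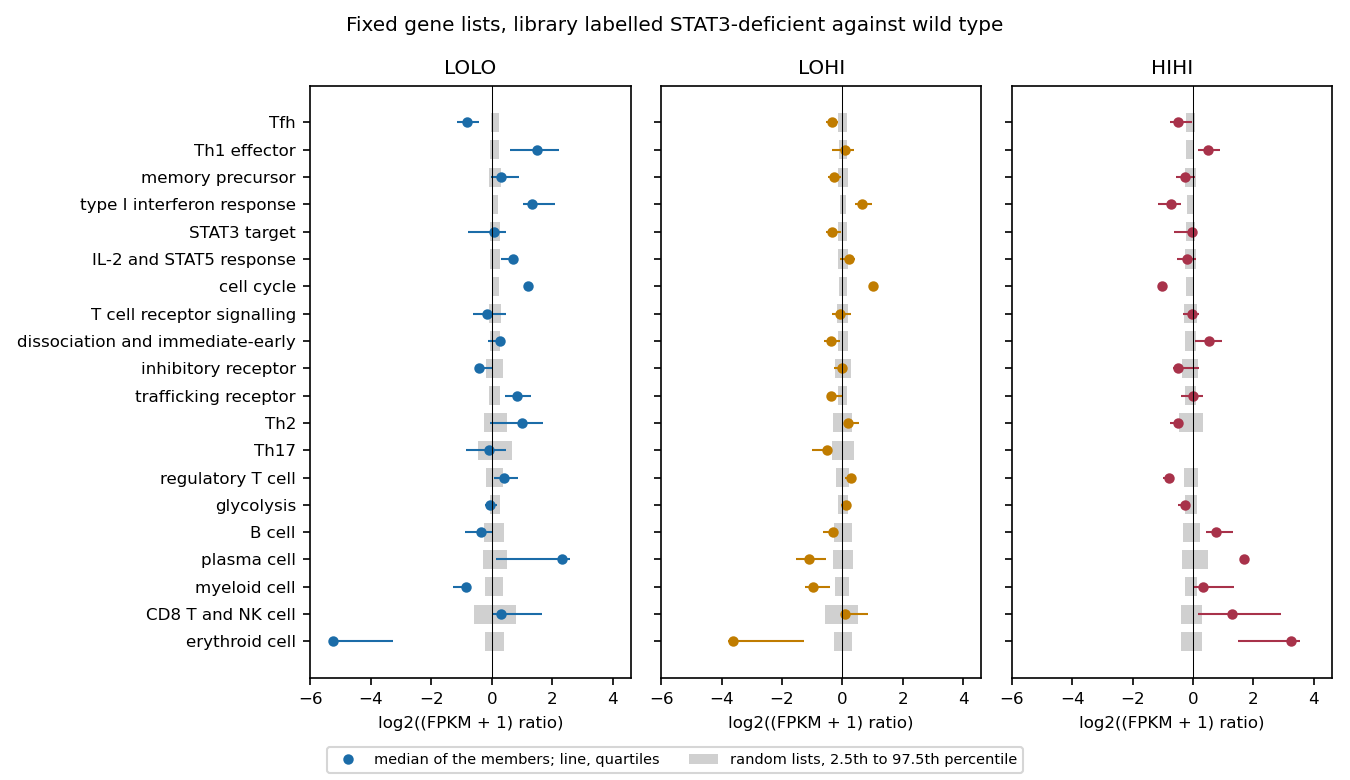
Median log2((FPKM + 1) ratio) of each fixed gene list between the library labelled STAT3-deficient and the wild-type library, in LOLO, LOHI and HIHI from left to right, with quartiles of the members as lines and the range of matched random lists as grey bars; Th17 had too few measured members in HIHI to be drawn. The cell cycle list stands at 1.19, 0.997 and -1.03, and the Tfh list at -0.83, -0.34 and -0.50.

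The LOHI comparison puts the same question to central memory precursors. In the LOHI library labelled STAT3-deficient, interferon-response and cell cycle genes were higher, and Tfh, trafficking receptor and STAT3 target genes were lower by small amounts. Birc5, the mitotic survivin gene, was at 141 FPKM against 61.0, and Ifit3 at 16.0 against 2.95. Gzmk was at 114 FPKM against 27.2 and Klrk1, which encodes the activating receptor NKG2D, at 17.7 against 3.38. Of 11353 genes counted, 745 differed at least 2-fold, 340 higher and 405 lower. With ordinary genes alone the split turned, to 127 higher and 56 lower of 8339.

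Of the 33 cell cycle genes, 15 were at least 2-fold higher and 0 lower, with a median of 0.997, above all random lists. Bub1b, a spindle checkpoint kinase, was at 88.7 FPKM against 38.2, and Cdk1 at 170 against 77.3. Of the 52 interferon-response genes, 11 were at least 2-fold higher and 0 lower (median 0.65), led after Ifit3 by Ifi44 (7.92 against 1.51 FPKM), Rsad2 (12.4 against 3.14) and Oasl1 (20.8 against 5.78). Xcl1 was at 29.1 FPKM against 4.42. The Tfh list had a median of -0.34 at percentile 0, with 2 of 24 measured genes at least 2-fold lower, Angptl2 (8.26 against 18.6 FPKM) and Pou2af1 (7.10 against 15.4). Bcl6 was at 6.998 FPKM against 12.2. The STAT3 target list had a median of -0.33 and the Th17 list one of -0.50, both below the central range of random lists.

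The Th1 effector list was not apart in LOHI, with a median of 0.08 at percentile 84.1, and Tbx21 was at 64.0 FPKM against 58.3. The trafficking receptor list had a median of -0.38, with Ccr2, a receptor for inflammatory chemokines, at 17.2 FPKM against 62.6. The memory precursor list had a median of -0.29, with Satb1 at 64.3 FPKM against 183 and Ccr7, which guides cells into T cell zones, at 35.5 against 56.2. The IL-2 and STAT5 response (0.21) and regulatory T cell (0.29) lists lay above the central range of random lists. The dissociation and immediate-early list had a median of -0.38, and the heat shock gene Hspa1a was at 17.4 FPKM against 79.1. Globin, plasma cell and myeloid transcripts were lower as well, with medians of -3.62, -1.12 and -0.97, and Hba-a1 was at 12.4 FPKM against 180. Lmbr1 was at 0.576 FPKM against 31.7, and Slpi, a protease inhibitor of myeloid and epithelial cells, at 4.95 against 38.9. A second model with the symbol Yars (ENSMUSG00000088921), listed at 0 in wild-type LOHI, had 80.3 FPKM. The authors' deposited table marks 98 genes for this pair, 41 higher and 57 lower.

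In HIHI, the terminal effector population, interferon-response and cell cycle genes were lower in the library labelled STAT3-deficient, opposite to LOLO and LOHI. That contrast between populations was not tested. Gene-level Stat3, which does not check the deletion, differed here by 0.26 (log2), or by 0.03 with equal sums. Ifit3 was at 3.36 FPKM against 16.4, and Birc5 at 63.1 against 149. Some Th1 effector genes were higher: Gzma, a granzyme, was at 347 FPKM against 50.7 and Prf1, the pore-forming perforin, at 29.4 against 9.60. Transcripts of CD8 T cells, plasma cells and red cells were also higher, with Cd8a at 35.3 FPKM against 1.27. Of 11344 genes counted, 907 differed at least 2-fold, 538 higher and 369 lower, a split of 59.3 percent higher that became 43.1 percent when libraries were scaled to equal sums. Of ordinary genes alone, 304 of 8347 differed, 129 higher and 175 lower.

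Of the 33 cell cycle genes, 18 were at least 2-fold lower and 0 higher in HIHI, with a median of -1.03 at percentile 0. Rrm1, a subunit of ribonucleotide reductase, was at 32.2 FPKM against 75.7, and Ccna2, which encodes cyclin A2, at 48.2 against 110. Of 51 measured interferon-response genes, 17 were at least 2-fold lower and 0 higher (median -0.74), among them Ifi44 (2.76 against 12.6 FPKM), Oasl2 (3.79 against 15.1) and Oasl1 (6.52 against 20.6). The Th1 list had a median of 0.48, above all random lists, with 6 of 31 genes at least 2-fold higher. That median was 0.25 when libraries were scaled to equal sums, and the CD8 T and NK cell list was higher in the same pair, with a median of 1.30. The 6 Th1 genes included Cx3cr1, a receptor of terminal effector cells (41.5 against 10.9 FPKM), and Ccl4 (131 against 45.2). Gzmk, also of this list, was at 77.9 FPKM against 124, and Gzmb at 324 against 259. The Tfh list had a median of -0.50 at percentile 0, with Tox at 16.2 FPKM against 50.9 and Pdcd1, the gene of PD-1, at 29.6 against 61.7. Il21 was at 7.31 FPKM against 14.3 and Cxcr5 at 11.3 against 17.4. Bcl6 was at 4.72 FPKM against 3.86, a log2 difference of 0.23 that was 0.042 when libraries were scaled to equal sums.

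The regulatory T cell list had a median of -0.80, with Foxp3 at 2.19 FPKM against 5.67 and Ikzf2, which encodes Helios, at 10.02 against 24.5. The inhibitory receptor (-0.49), Th2 (-0.48) and glycolysis (-0.27) lists also lay below the central range of random lists. The memory precursor, STAT3 target, IL-2 and STAT5 response, T cell receptor signalling and trafficking receptor lists were not apart. Within the last, Ccr2 was at 110 FPKM against 34.3. Plagl1 (2.99 against 22.1 FPKM) and Xcl1 (4.97 against 27.3) were among the 8 lowest genes. The dissociation and immediate-early list had a median of 0.52, with Hspa1a at 109 FPKM against 27.7 and Jun at 506 against 221.

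Markers of other cells stood beside these in HIHI. The plasma cell list had a median of 1.68, with Igkc at 119472 FPKM against 35826, Igj, the joining chain of secreted antibody, at 3854 against 1260, and Sdc1, a plasma cell surface proteoglycan, at 60.2 against 15.8. Immunoglobulin models took 21.5 percent of summed FPKM against 8.19 percent. The CD8 T and NK cell list had a median of 1.30, with Cd8b1 at 96.4 FPKM against 9.03. The B cell (0.77), myeloid (0.34) and erythroid (3.24) lists were above the central range of random lists as well. Cd79a, part of the B cell receptor, was at 33.9 FPKM against 8.25, Itgax, the gene of CD11c, at 40.0 against 4.07, and Hba-a1 at 162 against 12.4. The authors' deposited table marks 146 genes for this pair, 108 higher and 38 lower.

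**Figure D2:**
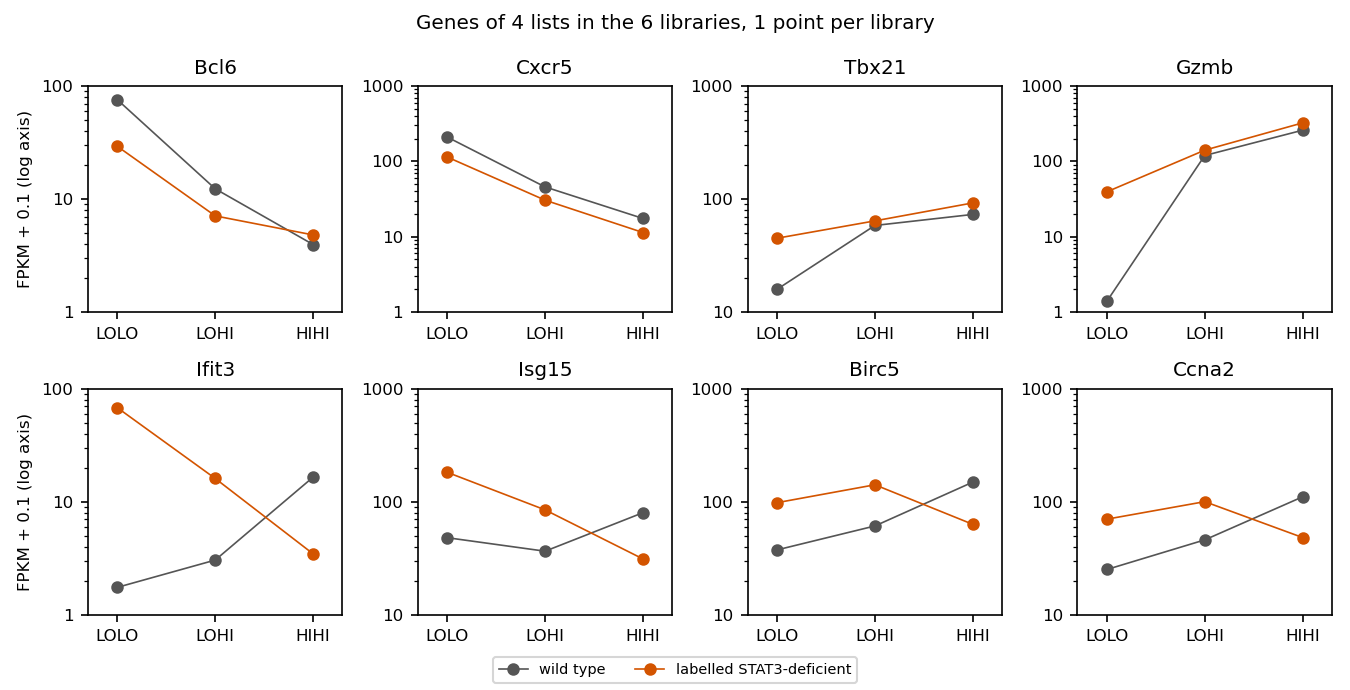
FPKM plus 0.1 on a log axis of 8 genes in the 6 libraries, with population on the horizontal axis, wild type in grey and the libraries labelled STAT3-deficient in orange; each point is 1 library and the lines only join the points of a genotype. Bcl6 and Cxcr5 descend from LOLO to HIHI in both genotypes, while the lines of Ifit3, Isg15, Birc5 and Ccna2 cross between LOHI and HIHI.

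The genotype differences were then compared between populations over the 10441 genes counted in all 3. Across genes, which are not independent replicates, Spearman's rho was 0.58 between LOLO and LOHI, -0.41 between LOLO and HIHI and -0.66 between LOHI and HIHI. Pearson's r over the same genes was 0.25, 0.029 and -0.38. Over all genes, the opposition of LOLO and HIHI thus shows in the rank correlation and not in the linear one. At least 2-fold higher in all 3 populations were 9 genes and lower were 5, against 0.257 and 0.109 for independent lists, and 0 of them had an ordinary symbol. By contrast, 84 genes were higher in LOLO and LOHI and lower in HIHI, against 0.307 for independent lists, and 65 of these had an ordinary symbol. They included Ifit3, Isg15, Cxcl10, Xcl1, Birc5 and Ccna2. The reverse held for 36 genes, 11 with an ordinary symbol, among them Hba-a1, Hbb-b1, C1qa, a complement gene of macrophages, and Hspa1a. A further 49 genes, 1 with an ordinary symbol (Igj), were higher in LOLO and HIHI and lower in LOHI, against 0.239 for independent lists. The remaining mixed directions held 7 genes or fewer each, 0 with an ordinary symbol. Cxcl10 and the members of these groups outside the naming rule were chosen after their values were seen.

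**Figure D3:**
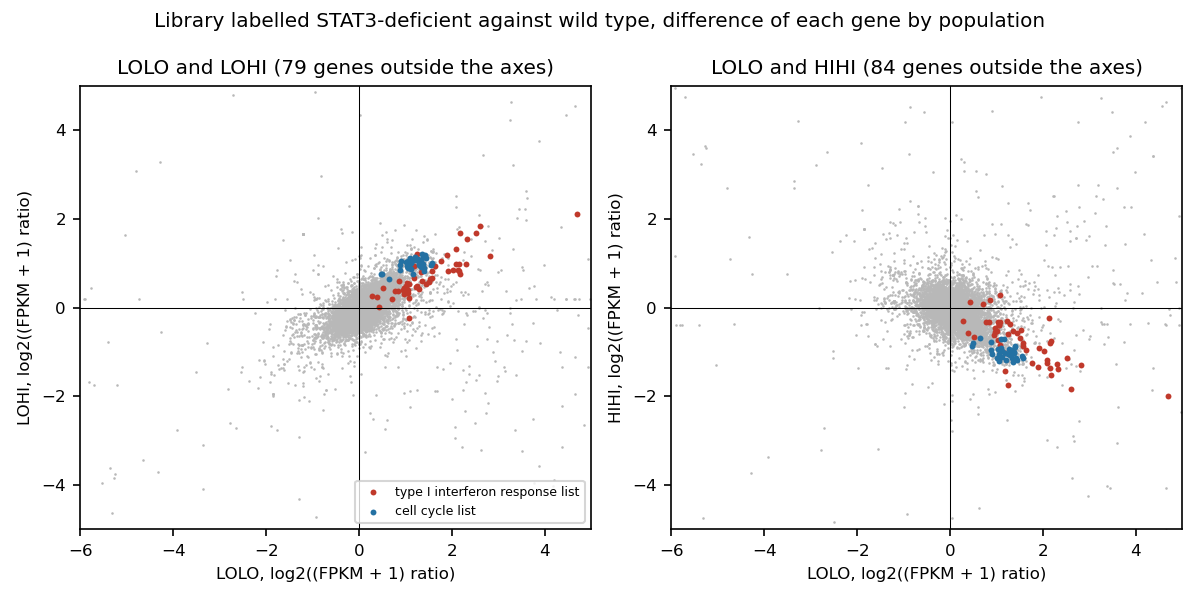
Log2((FPKM + 1) ratio) of each gene between the library labelled STAT3-deficient and the wild-type library, with LOLO on the horizontal axes and LOHI (left) or HIHI (right) on the vertical axes; each point is a gene counted in all 3 populations. Interferon-response (red) and cell cycle (blue) genes lie mostly in the upper right on the left, where Spearman's rho over all genes is 0.58 and Pearson's r 0.25, and mostly in the lower right on the right, where these are -0.41 and 0.029.

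The wild-type libraries give the differences between the populations themselves. LOLO against HIHI sets follicular helper cells against terminal effectors: Bcl6 was at 75.5 FPKM against 3.86, Cxcr5 at 210 against 17.4 and Il21 at 160 against 14.3. Gzmb was at 1.29 FPKM in LOLO and 259 in HIHI, Ccl5 at 42.2 and 1407, and Tbx21 at 15.8 and 73.0. Of 11520 genes counted, 1836 differed at least 2-fold, 657 higher and 1179 lower in LOLO. Of ordinary genes alone, 1028 of 8536 differed, 367 higher and 661 lower.

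Of the 25 Tfh genes, 19 were at least 2-fold higher in wild-type LOLO and 0 lower, with a median of 1.75. Sostdc1, a secreted antagonist of BMP and Wnt signals, was at 115 FPKM against 2.60, Tox2 at 247 against 14.1 and Ascl2 at 13.9 against 0.0912. Of the 31 Th1 effector genes, 25 were at least 2-fold lower and 0 higher, with a median of -2.84. Cell cycle genes were lower in LOLO, 31 of 33 at least 2-fold (median -1.59), as were 21 of 52 interferon-response genes (median -0.93), among them Oas2 at 0.580 FPKM against 10.9. The inhibitory receptor list had a median of 1.59, with Pdcd1 at 292 FPKM against 61.7 and Btla at 101 against 29.3. The STAT3 target (0.35), T cell receptor signalling (0.53), Th17 (0.93) and glycolysis (0.52) lists lay above the central range of random lists, with Egr2 at 76.4 FPKM against 15.6. The trafficking receptor (-1.17), IL-2 and STAT5 response (-0.93), memory precursor (-0.54) and dissociation and immediate-early (-0.56) lists lay below it. Prdm1 was at 0.675 FPKM against 17.2.

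Other cells' transcripts differed too. Igkc was at 264 FPKM in wild-type LOLO and 35826 in HIHI, Lyz2, the lysozyme of myeloid cells, at 2.22 and 60.2, and Hba-a1 at 2001 and 12.4. The plasma cell, B cell, myeloid and erythroid lists had medians of -4.27, -1.85, -0.96 and 6.90. The authors' deposited table marks 760 genes for this pair, 239 higher and 521 lower in LOLO.

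LOLO against LOHI in wild type, follicular helper cells against memory precursors, gave a smaller set. Gzmb was at 1.29 FPKM in LOLO and 119 in LOHI, Ccr2 at 0.466 and 62.6, and Il7r, the IL-7 receptor that sustains memory cells, at 6.15 and 46.8. Il21 was at 160 and 25.3 FPKM, and Cebpa, a transcription factor of the Tfh list, at 48.2 and 4.43. Of 11347 genes counted, 1198 differed at least 2-fold, 419 higher and 779 lower. Of ordinary genes alone, 536 of 8413 differed, 198 higher and 338 lower.

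Of the 25 Tfh genes, 17 were at least 2-fold higher in LOLO (median 1.26), and of the 31 Th1 genes 24 were lower (median -2.16). The memory precursor list had a median of -0.997, with Klf2, a regulator of T cell egress, at 46.9 FPKM against 182. The trafficking receptor (-1.47), Th17 (-1.06), cell cycle (-0.66) and interferon-response (-0.24) lists lay below the central range of random lists. Foxp3 was at 1.504 FPKM against 9.24. The STAT3 target list had a median of -0.28, which was 0.20 over members with at least 5 FPKM. Globin genes were higher in LOLO (erythroid median 3.43) and plasma cell genes lower (-2.23). The dissociation and immediate-early list had a median of -0.60, below the central range of random lists. Mitochondrial genes took 14.2 percent of summed FPKM in LOLO and 6.27 percent in LOHI. The authors' deposited table marks 397 genes, 134 higher and 263 lower.

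LOHI against HIHI in wild type sets memory precursors against terminal effectors. Ly6c2 was at 46.0 FPKM in LOHI and 1567 in HIHI, Klrk1 at 3.38 and 28.9, and Gzmk at 27.2 and 124. Tcf7, which encodes the memory-associated factor TCF-1, was at 696 and 331 FPKM, and Satb1 at 183 and 82.3. Of 11417 genes counted, 903 differed at least 2-fold, 316 higher and 587 lower. Of ordinary genes alone, 284 of 8385 differed, 80 higher and 204 lower.

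The memory precursor (0.39), Tfh (0.65), STAT3 target (0.36) and Th17 (1.13) lists were above the central range of random lists in LOHI, with Il22 at 4.87 FPKM against 0.348. The Th1 (-0.49), interferon-response (-0.68) and cell cycle (-1.003) lists were below it. Granule genes of myeloid precursors were among the 8 lowest: Prtn3 was at 1.90 FPKM against 70.7, Mpo at 3.80 against 76.5 and Elane at 1.17 against 32.5. Plasma cell (-2.15), B cell (-1.52), myeloid (-0.55) and CD8 T and NK cell (-0.98) lists were lower in LOHI and the erythroid list higher (3.44). The authors' deposited table marks 275 genes, 32 higher and 243 lower.

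The libraries labelled STAT3-deficient were compared in the same way to see which population differences remained. Between LOLO and HIHI, Bcl6 was at 29.2 FPKM against 4.72, Cxcr5 at 114 against 11.3 and Il21 at 64.3 against 7.31. Gzma was at 14.8 FPKM against 347 and Gzmb at 39.4 against 324. Interferon-response genes, lower in LOLO than HIHI in wild type, were higher in this pair, with Ifit3 at 67.8 FPKM against 3.36. Of 11573 genes counted, 1626 differed at least 2-fold, 689 higher and 937 lower. That split of 42.4 percent higher became 68.2 percent when libraries were scaled to equal sums. Of ordinary genes alone, 867 of 8512 differed, 432 higher and 435 lower.

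Of the 25 Tfh genes, 18 were at least 2-fold higher and 1 lower in this LOLO library (median 1.90). Sostdc1 was at 51.1 FPKM against 1.37, Tox2 at 131 against 10.2 and Tox at 146 against 16.2. Of the 31 Th1 genes, 22 were at least 2-fold lower and 1 higher (median -1.97), with Klrg1, a terminal effector receptor, at 3.75 FPKM against 49.5. Of 51 interferon-response genes, 27 were at least 2-fold higher and 1 lower (median 1.22), and the cell cycle list had a median of 0.63. Pdcd1 was at 216 FPKM against 29.6 and Batf, an AP-1 factor of Tfh cells, at 388 against 103. The regulatory T cell (0.85) and glycolysis (0.70) lists lay above the central range of random lists, with Ikzf2 at 61.9 FPKM against 10.02. The dissociation and immediate-early list had a median of -1.18, with Hspa1a at 9.58 FPKM against 109. Plasma cell (-4.71), myeloid (-1.91), CD8 T and NK cell (-2.27) and B cell (-1.79) lists were lower in LOLO. The authors' deposited table marks 895 genes, 337 higher and 558 lower.

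LOLO and LOHI labelled STAT3-deficient were the closest pair of populations within a genotype, by the count of genes. Selplg was at 25.6 FPKM in LOLO and 253 in LOHI, Bcl6 at 29.2 and 6.998, and Gzmb at 39.4 and 141. Of 11273 genes counted, 630 differed at least 2-fold, 313 higher and 317 lower, and 174 of 8346 with ordinary genes alone, 103 higher and 71 lower. Of the 25 Tfh genes, 10 were at least 2-fold higher (median 0.95) and of the 31 Th1 genes 8 were lower (median -0.79). Cebpa was at 20.9 FPKM against 2.80 and Klrd1, an NK cell receptor chain, at 11.4 against 36.9. Interferon-response genes were higher in LOLO (median 0.46) and cell cycle genes lower (-0.37). Among other cells' lists, the erythroid list was higher (1.71) and the B cell list lower (-0.30), both outside the central range of random lists. The Th2 list had a median of 0.30 that was -0.12 over members with at least 5 FPKM. The authors' deposited table marks 94 genes, 53 higher and 41 lower.

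Between LOHI and HIHI labelled STAT3-deficient, cell cycle genes were higher in LOHI, the opposite of wild type, with a median of 1.02 and Bub1b at 88.7 FPKM against 36.0. The interferon-response list had a median of 0.70 and the regulatory T cell list one of 1.11, with Foxp3 at 10.1 FPKM against 2.19. The Th1 list had a median of -0.95 with 15 of 31 genes at least 2-fold lower, among them Gzma (28.0 against 347 FPKM) and Zeb2, a terminal effector factor (3.78 against 25.1). Of 11466 genes counted, 1277 differed at least 2-fold, 526 higher and 751 lower, a split of 41.2 percent higher that became 64.0 percent when libraries were scaled to equal sums. Of ordinary genes alone, 544 of 8410 differed, 281 higher and 263 lower. Plasma cell (-5.18), myeloid (-1.84), B cell (-1.83), erythroid (-3.42) and CD8 T and NK cell (-1.74) lists were lower in LOHI. So was the dissociation and immediate-early list (-0.81). Slpi was at 4.95 FPKM against 1600. The authors' deposited table marks 585 genes, 123 higher and 462 lower.

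**Figure D4:**
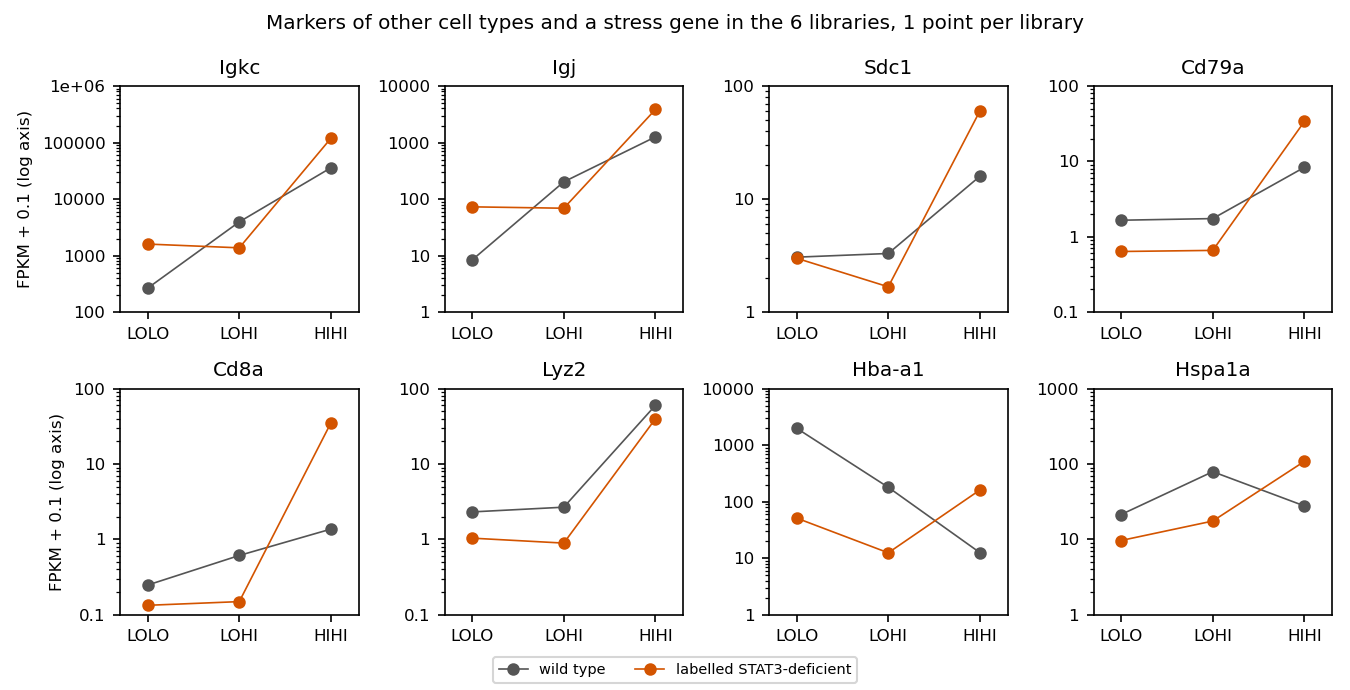
FPKM plus 0.1 on a log axis of 7 markers of other cell types and the heat shock gene Hspa1a in the 6 libraries, with population on the horizontal axis, wild type in grey and the libraries labelled STAT3-deficient in orange; each point is 1 library. Igkc reaches 35826 and 119472 FPKM in the HIHI libraries, Hba-a1 2001 FPKM in wild-type LOLO, and Cd8a 35.3 FPKM in the HIHI library labelled STAT3-deficient.

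The LOLO against HIHI difference of each gene was then set against itself in the other genotype, over 11067 genes counted in both. Spearman's rho across genes was 0.25 and the slope of the labelled STAT3-deficient on the wild-type difference was 0.61. Of the 1616 genes at least 2-fold apart in wild type, 69.1 percent had the same direction in the labelled libraries. At least 2-fold apart in both were 711 genes the same way and 144 in opposite ways. For each gene, the difference of these differences equals the genotype difference in LOLO minus that in HIHI. It is therefore not a separate result, and it rests on the HIHI labels. By list, its median over the members was 2.18 for interferon-response and 2.23 for cell cycle genes. With the labels as given, both lists turned from lower to higher in LOLO. The same median was 1.01 for Th1 and -0.47 for Tfh genes, and both of these lists kept their direction. For Tfh genes the quartiles of the difference of differences, -0.83 and 0.52, span 0. The Tfh list median was 1.75 in wild type and 1.90 in the labelled libraries.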

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

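Of the tests in this part, those of the interferon-response genes against a mixture, of a scale difference between the LOLO libraries and of dilution by CD8 T cells were chosen only after the result was seen, as were the demand that the Th1 mixing share lie outside its resampling interval and the limit of the pan-T cell test to cells other than T cells.

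In each contrast below, a fixed list stood apart from random lists in opposite directions by genotype in a pair of populations; each group had 1 library, and the differences were not tested. The interferon-response median was lower in HIHI than in LOLO by genotype, with a log2 difference of -2.05, and than in LOHI, with -1.39. For cell cycle genes these values were -2.21 and -2.02, and for regulatory T cell genes -1.19 and -1.09. Th2 genes gave -1.49 between HIHI and LOLO. Dissociation and immediate-early genes gave 0.91 between HIHI and LOHI, and trafficking receptors -1.21 between LOHI and LOLO. Among other cells' genes, HIHI minus LOLO and HIHI minus LOHI were 1.12 and 1.09 for B cells, 1.19 and 1.31 for myeloid cells, and 8.50 and 6.86 for erythroid cells. Plasma cell genes gave -3.42 for LOHI minus LOLO and 2.79 for HIHI minus LOHI.

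The genotype difference of interferon-response, cell cycle and globin genes had the opposite sign in HIHI, while that of Th1 and Tfh genes did not. Dilution by cells other than T cells was argued against by 15 pan-T cell genes. Their median log2 difference in HIHI was 0.0046, with quartiles of -0.03 and 0.13. Dilution by CD8 T cells, which share those genes, was argued against less firmly, by 3 genes of the CD4 lineage. Their median was 0.20 and the lowest value, that of Cd4, was -0.22. All these values lay above the interferon-response median of -0.74. With equal sums, however, Cd4 was at -0.45 and the interferon-response median at -0.95. The same 3 genes also had a median of -0.52 in LOHI, although Cd8a was lower there, at 0.050 FPKM against 0.513. An exchange of the HIHI genotype labels cannot be told apart from labels as given. The test took 195 genes within 10 Mb of Stat3. It assumed that they travel with the engineered allele and differ with it, which was not checked. A difference counted from 0.32 (log2), a smaller size than the 2-fold used elsewhere. With the labels exchanged, 14.4 percent of them differed the same way in all 3 populations, against 12.3 percent of 10246 others. That share was above 73.0 percent of 63 other windows. Its genes included Top2a, Dhx58 and Ifi35, of the cell cycle and interferon-response lists themselves. With the labels as given these shares were 0 of 195 and 0.800 percent, so neither set of labels set the window apart. The Tfh list is lower in all 3 populations with the labels as given (-0.83, -0.34 and -0.50), though Bcl6 itself is not lower in HIHI (0.23), and the Th1 list is higher in LOLO and HIHI (1.48 and 0.48), though in HIHI it moves with the CD8 T and NK cell list (1.30). The interferon-response, cell cycle and globin genes line up across populations only once the labels are exchanged. The same holds for gene-level Stat3, at -0.15, -0.20 and 0.26 in LOLO, LOHI and HIHI. Its HIHI value is 0.03 with equal sums, and it does not check the deletion. The opposition is wider than these lists. Without short or unnamed models, receptor segments, mitochondrial genes, other cells' markers, interferon-response and cell cycle genes, Spearman's rho was 0.64 between LOLO and LOHI. It was then -0.45 between LOLO and HIHI and -0.70 between LOHI and HIHI. A role of STAT3 that differs by population stays open and was not tested.

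Th1 and interferon-response genes were higher in the LOLO library labelled STAT3-deficient. A scale difference was argued against by the median of all counted genes, 0.12, far below the list medians of 1.48 and 1.32. PSGL-1-high cells as the source of the interferon-response part were argued against because 36 of 41 members, 87.8 percent, lay above all LOHI and HIHI libraries. Those 41 were picked for being at least 2-fold higher in that same library, which raises the share. Over all measured members, the list median in LOLO was 0.46 above LOHI and 1.22 above HIHI among the labelled libraries. For the Th1 part, shares of LOHI cells with the wild-type libraries as sources do not tell PSGL-1-high cells apart from expression in LOLO cells. There, 86 other genes gave a share of 24.2 percent of LOHI cells, below the Th1 members' lower quartile of 27.1. The resampling interval of that share, 18.9 to 29.1, holds the quartile. Selplg was at 25.6 FPKM where such a mixture would give 156, and at 253 and 480 FPKM in LOHI and HIHI labelled STAT3-deficient. As the gene of the sorted protein it argues against a mixture of that size, though it is 1 gene in 1 library. The sort on PSGL-1 should remove these cells, and an effect of STAT3 stays open, untested.

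Immunoglobulin transcripts were high in HIHI and higher in the library labelled STAT3-deficient, with Igkc at 119472 FPKM against 35826 and Igj at 3854 against 1260. Plasma cells, or RNA from them, are a candidate source: 20 secretory-pathway genes had a median log2 difference of 0.71, above all random lists. The gate on CD4 and CD44 should remove such cells. Of these genes 19 were also expressed at 1 FPKM or more in both LOLO libraries, and 0 belong to a fixed list. A difference in plasma cells between the genotypes stays open and was not tested.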

How the results depend on the processing

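The count without short or unnamed models, segments, mitochondrial genes and other cells' markers, the matching alternative across populations and the use of status OK only were chosen after seeing the data. No paired analysis was possible because each comparison sets 1 library against 1 library, so no replicate numbers pair within it. A fit of genotype with population as a term, which assumes the same genotype difference in all 3 populations, was not run. Absolute depth is unknown, and wild-type LOLO, at 0.411 of the depth of wild-type LOHI, limits low genes the most.

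Of 82 alternative counts of genes at least 2-fold apart, 65 stayed within 1.5 times the reported count and 17 did not. With at least 20 FPKM, which admits fewer genes, the counts were 628 for genotype in LOLO, 433 in LOHI, 1124 for wild-type LOLO against HIHI, 695 for LOLO against LOHI and 546 for LOHI against HIHI. In the libraries labelled STAT3-deficient these were 1010, 335 and 829. Without the models and markers named above they were 478, 183 and 304 by genotype in LOLO, LOHI and HIHI, 1028, 536 and 284 in wild type, and 867, 174 and 544 in the labelled libraries. Counts with no minimum equal those at 1 FPKM by construction.

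Of 899 list results, 873 kept their direction and side of the threshold, 14 became weaker, 10 stronger and 2 reversed. Both reversed over members with at least 5 FPKM: STAT3 targets between wild-type LOLO and LOHI, to 0.20, and Th2 genes between LOLO and LOHI labelled STAT3-deficient, to -0.12. Of 2921 results of named genes, 2801 were the same, 89 weaker and 31 stronger.

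Across populations, 19 of 28 values moved and 0 reversed. With a pseudocount of 0.1, Spearman's rho between LOLO and HIHI was -0.40. At 1 FPKM rho was 0.52 for LOLO and LOHI, -0.36 for LOLO and HIHI and -0.60 for LOHI and HIHI. At 20 FPKM these were 0.61, -0.44 and -0.70, and without the models, markers, interferon-response and cell cycle genes 0.64, -0.45 and -0.70. The 14 genes apart the same way in all 3 populations became 9 at 20 FPKM and 0 without those models and lists. For the population difference in both genotypes, the slope was 0.53 and 0.66 with pseudocounts of 0.1 and 5, 0.58 at 1 FPKM and 0.65 at 20 FPKM. Its rho was 0.24 with a pseudocount of 5, 0.27 at 1 FPKM and 0.24 at 20 FPKM. The cause of these moves was not tested.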

Other observations

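The tests of the pan-T cell and secretory-pathway genes in this part were chosen only after the results of the fixed lists were seen. The 15 pan-T cell genes, of which 1 is also in a fixed list, were lower by genotype in LOLO (median log2 difference -0.25) and LOHI (-0.34), both below the 2.5th percentile of random lists. Between wild-type LOLO and HIHI they were higher in LOLO, with a median of 0.55. In the libraries labelled STAT3-deficient that median was 0.19, at percentile 48.8 and so not apart. Secretory-pathway genes were lower in LOLO than HIHI in both genotypes, with medians of -0.80 in wild type and -1.44 in the libraries labelled STAT3-deficient.

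Between LOLO and HIHI, the Th2 list had a median of -0.61 in wild type and 0.88 in the labelled libraries, and the regulatory T cell list -0.24 and 0.85. Neither of these wild-type values was apart from random lists, at percentiles of 3.70 and 13.3. The erythroid list had medians of 6.90 and -1.64, both apart. The CD8 T and NK cell list was at -1.04 and -2.27 over the 6 members compared, and it was not apart in wild type. These contrasts have no replicate check and were not tested.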
